A study of Homo sapiens with 6 samples.

How the data were processed

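Messenger RNA was measured by bulk RNA sequencing in 6 libraries of human umbilical vein endothelial cells, primary cells that line the vein of the umbilical cord. Per the labels, 3 libraries came from cells given 5 mM L-glucose and 3 from cells given 5 mM glucosamine, each for 6 hours under 2% oxygen without serum. Total RNA was used, 800 ng per library, with a SMARTER mRNA sequencing kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures or donors. The p-values of the gene tests therefore measure only the spread between these libraries, which can be technical. The bootstrap intervals and the permutation p of the closing observations resample genes or features, with the fold changes of these 6 libraries fixed. They do not cover spread between libraries or cultures.

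The values are the authors' normalized counts, a signal never below 0, deposited as 1 table with 62757 rows, 1 column per library and gene symbols as row names. Per the submitters' processing notes, bcl2fastq 2.20.0, FastQC 0.12.1 and HTSeq were used with genome build GRCh38.p13. The aligner, the annotation release, the strand setting of the counting and the tool behind the size factors are not given in the sources used here. In each column every value was a whole multiple of the smallest value above 0, so the whole reads per gene could be recovered: 100% of values came out whole, with a tolerance of 1e-06. The recovered totals in genes were 92.1, 84.5 and 91.0 M reads for L-glucose replicates 1, 2 and 3 and 86.0, 83.2 and 82.9 M for glucosamine replicates 1, 2 and 3. The authors' scaling gave the glucosamine libraries higher totals of normalized counts, 89.6 M ± 0.058 (SD, n = 3) against 82.5 M ± 1.76 for L-glucose.

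Symbols were matched to GENCODE release 29 on GRCh38 for positions and gene types, and 56949 rows matched. Of all rows, matched or not, 20938 carried an Ensembl identifier without a symbol, and their genes were counted but not named. Before any test, 511 rows of Y-linked genes and of RNA genes of X inactivation were left out, and other genes on chromosome X were kept. Library pairs within a group differed by more than counting error (chi-square per degree of freedom 2.80 to 11.2), so no library was a copy of another.

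The comparison of glucosamine with L-glucose used limma 3.58.1 in R 4.3.3 (limma-trend, 2-sided) on log2 of the normalized count plus 1, over 24958 genes with a mean of at least 10 over the 6 libraries. Adjusted p-values are Benjamini-Hochberg values from limma, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Errors of log2 fold changes are standard errors from the fit. Counting with HTSeq can split or drop reads of near-identical copies, so values of HSPA1A and HSPA1B, ZDHHC11, the U1, U2 and U3 RNA genes and histone genes are uncertain, as are those of overlapping and antisense genes.

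The 36 gene lists were fixed before the data were examined, from the series title, the design text and general knowledge of stress, cell cycle and cell types, and 33 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists. Beside it, camera with a correlation estimated from the data was run, and fry, which asks only whether the genes of a list move, on balance, one way. For each list the members past the threshold were counted, adjusted over all genes and adjusted over the list alone. Named genes were also chosen by a rule fixed before the data were examined. It took, per direction, the 12 genes with the largest log2 fold change among those past the threshold with a symbol, a mean of at least 50 and no overlap between the groups. It added up to 4 members per list with the smallest adjusted p, and ATF4, VEGFA, HIF1A and GFPT1. Members that went against their list, and the genes of the closing observations, were named after their values were seen.

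Alternatives were another pseudocount (0.5 and 5), no filter or a mean of at least 50, TMM and upper-quartile scaling, the replicate number as a block, robust limma-trend, limma-voom, each library left out in turn, a minimum change of 2-fold, and count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Total-count scaling and a weight per group were added after seeing the data. On the recovered reads edgeR called 5810 genes higher and 5866 lower, and DESeq2 5060 higher and 5241 lower. The steps were tested on simulated counts for the 24958 genes of this comparison, with 50 genes changed at each size. The test recovered 38.0% of the genes changed 1.25-fold, 62.0% at 1.5-fold, 76.0% at 2-fold and 98.0% at 4-fold. It also called 9 unchanged genes, 6.16% of all its calls. A list raised 1.5-fold in simulated counts was called by camera (adjusted p = 1.7e-45) and, with an estimated correlation, at an adjusted p of 0.0031. At the preset correlation 0 of the other lists were called. Genes were simulated independently of each other, so this does not show how either camera test behaves when list members vary together. Tables were handled with Python 3.11.15 and pandas 2.3.3, positions compared with bedtools 2.31.1, and plots drawn with matplotlib 3.10.9.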

Results

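Gene expression was compared between human umbilical vein endothelial cells given glucosamine and cells given L-glucose. Glucosamine is D-glucose with an amino group in place of a hydroxyl group, and enters the hexosamine pathway, which makes the sugar donor for protein glycosylation. L-glucose is the mirror image of D-glucose and is not used by cells as fuel. Both were given at 5 mM for 6 hours, under 2% oxygen and without serum, with 3 libraries per group. The title of the series names the hexosamine pathway and ATF4, and its design text asks which genes lie behind the effect of glucosamine on vessel growth under low oxygen. Each library held between 82.9 and 92.1 M reads in genes. The 3 glucosamine libraries lay closer together than the 3 L-glucose libraries, with a median coefficient of variation of 2.21% against 3.90% over the 8789 genes with a mean above 1000.

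After glucosamine the cells had higher mRNA of nearly all tested genes of the integrated stress response, of amino acid supply and of the folding machinery of the endoplasmic reticulum. Most of the tested inflammatory and adhesion genes were higher too, while most genes of the heat shock response were lower. Of the 24958 genes tested, 5883 were higher and 5716 lower after glucosamine, and 13359 did not pass the limma threshold. Among them were 14143 protein-coding genes, 3938 of them higher and 4397 lower. Most changes were small: the median absolute log2 fold change of the called genes was 0.42, and 912 genes rose and 709 fell by at least 2-fold. The groups did not overlap in 13505 of the tested genes, where chance gives 10%, and 11174 of these were called. With total-count scaling the median of all genes moved from 0.01 to -0.11 and 31.5% of the calls were higher (3858 higher, 8398 lower) against 50.7%, so small changes below are relative to the authors' scaling. Of 33 tested gene lists, camera called 14 higher and 1 lower at its preset correlation; with an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, and fry called 25.

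The mRNA of ATF4, a transcription factor of the integrated stress response, rose from 21469 ± 594 to 66238 ± 509 normalized counts (SD, n = 3), a log2 fold change of 1.63 ± 0.03 (SE, limma adjusted p = 2.8e-20). ATF4 lies on chromosome 22 from 39519695 to 39522685 (GRCh38, GENCODE 29). Of the 21 tested members of the list of ATF4 and CHOP stress factors, 20 rose and 1 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 2.55. DDIT3, which encodes the stress factor CHOP (chromosome 12, 57516588 to 57521737), rose from 474 ± 37.8 to 11044 ± 75.9, a 23.3-fold change. The pseudokinase TRIB3 rose 15.3-fold, CHAC1, an enzyme that breaks down glutathione, 33.7-fold, and ADM2, a secreted peptide of the adrenomedullin family, 90.2-fold, from 29.3 ± 2.38 to 2730 ± 158. The member that fell was ATF5 (log2 fold change -0.17 ± 0.04). The list was past the threshold with camera (adjusted p = 3.9e-16) but not with an estimated correlation (adjusted p = 0.39 with an estimated correlation).

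Genes of amino acid synthesis and transport rose in 21 of 22 tested members and fell in 1, over all genes and adjusted over the list alone, with a median log2 fold change of 1.91. ASNS, which makes asparagine (chromosome 7, 97852118 to 97872542), rose from 44.8 ± 13.3 to 1712 ± 60.6 normalized counts, or 38.5-fold. SLC7A5, a transporter of large neutral amino acids, rose 12.5-fold, the glycine transporter SLC6A9 31.6-fold and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 15.4-fold. The mitochondrial folate enzyme MTHFD2 rose 9.51-fold, and ALDH18A1, an enzyme of proline synthesis, fell by 0.12 on the log2 scale, a call lost in each fit without 1 library except that without L-glucose replicate 2 (adjusted p between 0.057 and 0.13). The cytosolic aminoacyl-tRNA synthetases, which load amino acids on tRNA, rose in 18 of 20 members and fell in 1, RARS1 (log2 fold change -0.15), also when adjusted over the list alone. AARS1 had the largest log2 fold change of that list, 2.21 ± 0.04, followed by GARS1 with 1.80 ± 0.04; with total-count scaling 13 rose and 2 fell. Both lists were past the threshold with camera (adjusted p = 9.5e-17 and 9.6e-08) and neither with an estimated correlation (adjusted p = 0.39 and 0.51 with an estimated correlation).

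Every tested member of the list of ER chaperones and ER-associated degradation was higher after glucosamine (27 of 27, also adjusted over the list alone), with a median log2 fold change of 2.09. HSPA5, the main chaperone of the endoplasmic reticulum (chromosome 9, 125234853 to 125241330), rose from 81669 ± 4541 to 889416 ± 6978 normalized counts, or 10.9-fold. Its share of reads in genes was 0.10% in each L-glucose library and 0.993% ± 0.006 (SD, n = 3) after glucosamine. HERPUD1 and SEL1L, which act in the removal of misfolded proteins, rose 13.6-fold and 6.51-fold, and DERL3, of the same process, 39.2-fold. With total-count scaling 26 of the 27 were higher. The camera test gave an adjusted p of 2.8e-22, and the call was lost with an estimated correlation (adjusted p = 0.39 with an estimated correlation).

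**Figure D1:**
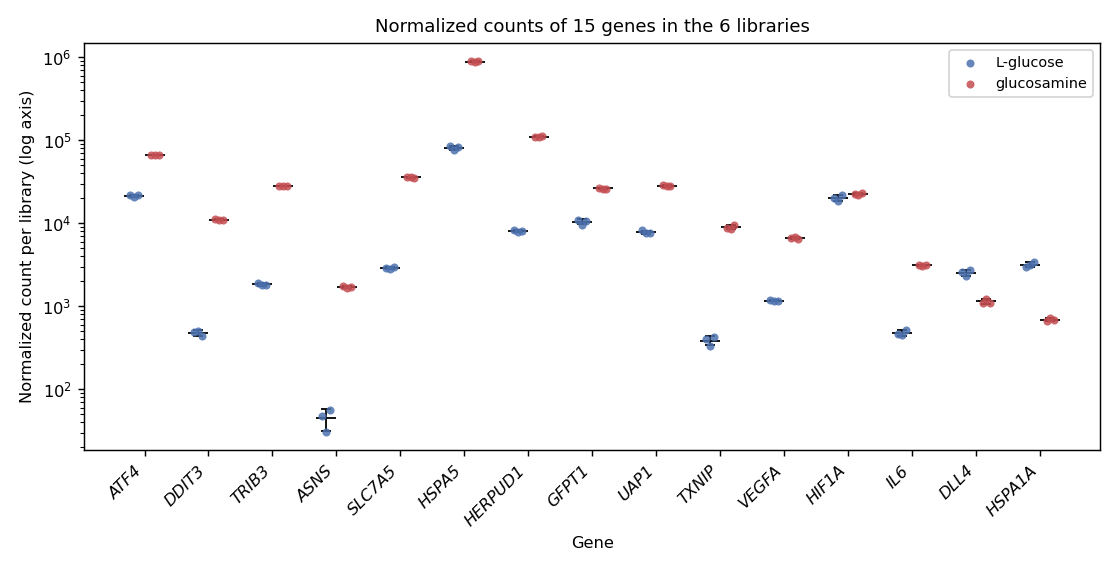
Normalized counts per library on a log axis for 15 genes, with L-glucose in blue and glucosamine in red (3 points each); horizontal marks are means and bars are SDs. ATF4 rises from 21469 to 66238 and HSPA5 from 81669 to 889416, while the points of HIF1A lie close together (20143 and 22459).

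In the hexosamine list, which covers the path from glucose or glucosamine to O-GlcNAc on proteins, 10 of 17 members rose and 2 fell. Adjusted over the list alone, 11 rose and 2 fell, and with total-count scaling 9 and 4. GFPT1, the rate-limiting enzyme of the pathway (chromosome 2, 69319769 to 69387254), rose from 10406 ± 742 to 26212 ± 585 normalized counts, a log2 fold change of 1.33 ± 0.04 (limma adjusted p = 1.1e-16). UAP1, which makes UDP-GlcNAc, rose 3.62-fold and OGT, the enzyme that adds O-GlcNAc, 2.23-fold. The glucose transporters SLC2A1 and SLC2A3 and the hexokinases HK1 and HK2, also in the glycolysis list, were among the members that rose. GFPT2 and NAGK were among those not called (log2 fold changes 0.01 and 0.02). GNPDA1 and AMDHD2, which turn amino sugars back toward glucose metabolism, fell by 0.33 and 0.17 on the log2 scale, and the AMDHD2 call was lost without L-glucose replicate 3 (adjusted p = 0.099) and without glucosamine replicate 1 or 3 (0.070 and 0.090). N-glycosylation enzymes rose in 19 of 32 members and fell in 3 (20 and 3 adjusted over the list alone, 16 and 5 with total-count scaling). RPN1 (log2 fold change 0.85) and STT3A (0.71) of the oligosaccharyltransferase and ALG5 (0.96) of lipid-linked sugar assembly were among those that rose. The lists had camera adjusted p-values of 0.0023 and 7.0e-05, and lost the call with an estimated correlation (adjusted p = 0.39 and 0.55 with an estimated correlation).

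TXNIP, which restrains glucose uptake and is a target of the sugar sensor MondoA (chromosome 1, 145992435 to 145996600), rose from 385 ± 46.4 to 8912 ± 502 normalized counts, or 23.2-fold. Its relative ARRDC4 rose 4.30-fold, and MLXIP, which encodes MondoA itself, fell by 0.52 on the log2 scale. Of the 6 tested members of the MondoA list 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.39 with an estimated correlation). The call was lost without L-glucose replicate 2 (adjusted p = 0.054) and over genes with a mean of at least 50 (0.067).

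VEGFA, the main growth factor of vessel sprouting (chromosome 6, 43770184 to 43786487), rose from 1167 ± 14.0 to 6632 ± 175 normalized counts (SD, n = 3), a log2 fold change of 2.50 ± 0.04 (limma adjusted p = 1.1e-21). HIF1A, the oxygen-regulated subunit of the hypoxia-inducible factor, had 20143 ± 1468 and 22459 ± 422 normalized counts, a log2 fold change of 0.16 ± 0.04 (adjusted p = 0.0034) that did not pass with total-count scaling (0.04). Among 31 tested HIF targets 14 rose and 8 fell, also when adjusted over the list alone, and the median log2 fold change was 0.08. With total-count scaling 12 rose and 14 fell, with a median of -0.03. NDRG1 rose 3.29-fold and HK2, the first enzyme of glycolysis, 1.98-fold. ADM, which encodes the vasodilator adrenomedullin, fell 2.35-fold and PFKFB4, a regulator of glycolysis, 2.06-fold. The list was not past the threshold with camera (adjusted p = 0.32) but was with edgeR (0.024) and DESeq2 (0.012) on whole reads and with fry (0.0011). Of 8 HIF subunits and regulators 3 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.74), with a median log2 fold change of 0.11 but a mean of -0.05; with total-count scaling 0 rose and 3 fell.

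Angiogenic ligands and receptors went both ways, with 7 of 29 members higher and 12 lower (7 and 13 adjusted over the list alone, 7 and 16 with total-count scaling). Beside VEGFA, CXCL8 rose 3.68-fold and FGF2 2.22-fold, while ADM fell. The list did not pass with camera (adjusted p = 0.49). Its median log2 fold change was -0.06 and its mean 0.01, and fry called it in the other direction, higher (adjusted p = 8.2e-04). Of 12 anti-angiogenic factors 4 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.68). VASH1, an inhibitor of vessel growth made by endothelial cells, fell from 8707 ± 496 to 3089 ± 162, or 2.82-fold. The median of that list was 0.01 on the log2 scale, its mean -0.15 and its camera direction lower. With total-count scaling 1 rose and 6 fell, with a median of -0.10, and fry called the list lower (adjusted p = 0.018).

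The Notch ligand DLL4, which limits sprouting (chromosome 15, 40929333 to 40939073), fell 2.21-fold, a log2 fold change of -1.15 ± 0.06 (limma adjusted p = 1.1e-12). JAG2, NRARP and LFNG of the same pathway fell by 0.69, 0.72 and 0.77 on the log2 scale, while HEY1 and JAG1 rose by 1.18 and 0.57. Of the 16 tested Notch genes 5 rose and 7 fell, and of 23 genes of endothelial identity 6 rose and 11 fell (6 and 12 adjusted over the list alone, and the Notch counts kept at 5 and 7). CLDN5, a tight junction protein, fell by 0.74 and the receptor TEK rose by 0.47 on the log2 scale. Neither list passed with camera (adjusted p = 0.41 and 0.25), and fry called both lower (0.022 and 0.017). With total-count scaling 4 Notch genes rose and 10 fell, and 2 and 14 genes of endothelial identity. KLF2 and KLF4, transcription factors induced by blood flow, rose 5.33-fold and 7.21-fold, and the connexin gene GJA4 fell 3.35-fold. In that list of 7 tested flow-responsive genes 3 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.49). It was called higher with edgeR and DESeq2 on whole reads and with fry.

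Inflammatory and adhesion genes of the NF-kB list rose in 20 of 23 members and fell in 1, over all genes and adjusted over the list alone, with a median log2 fold change of 1.12. The cytokine IL6 rose from 479 ± 39.5 to 3121 ± 30.8 normalized counts, or 6.52-fold, the adhesion molecule VCAM1 8.33-fold and the chemokine CXCL2 4.95-fold. CSF3 fell by 0.50 on the log2 scale (adjusted p = 0.034), a call that was lost without L-glucose replicate 1 or 3 and without glucosamine replicate 1 or 3 (adjusted p between 0.081 and 0.16). The camera test gave an adjusted p of 9.6e-08, and the call was lost with an estimated correlation (adjusted p = 0.44 with an estimated correlation). Of 21 interferon-stimulated genes 6 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.99). Their median log2 fold change was -0.04, their mean 0.01 and the camera direction lower; with total-count scaling 4 rose and 8 fell.

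The heat shock response, a list mostly of cytosolic chaperones and their partners, was the list that fell with camera (adjusted p = 1.8e-05, and adjusted p = 0.39 with an estimated correlation). Of its 13 tested members 11 fell and 2 rose, also when adjusted over the list alone, and the median log2 fold change was -0.43. HSPA1A (chromosome 6, 31815464 to 31817946) fell from 3180 ± 200 to 691 ± 31.5 normalized counts, or 4.59-fold, and its near-identical neighbour HSPA1B 3.28-fold. The co-chaperone DNAJA1 fell 2.31-fold and HSPH1 2.01-fold. The members that rose were the mitochondrial chaperonin HSPD1 and the cytosolic chaperone HSP90AB1, by 0.11 and 0.10 on the log2 scale, and both had values just below 0 with total-count scaling and lost the call without L-glucose replicate 2 or 3 and without glucosamine replicate 1 or 3.

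**Figure D2:**
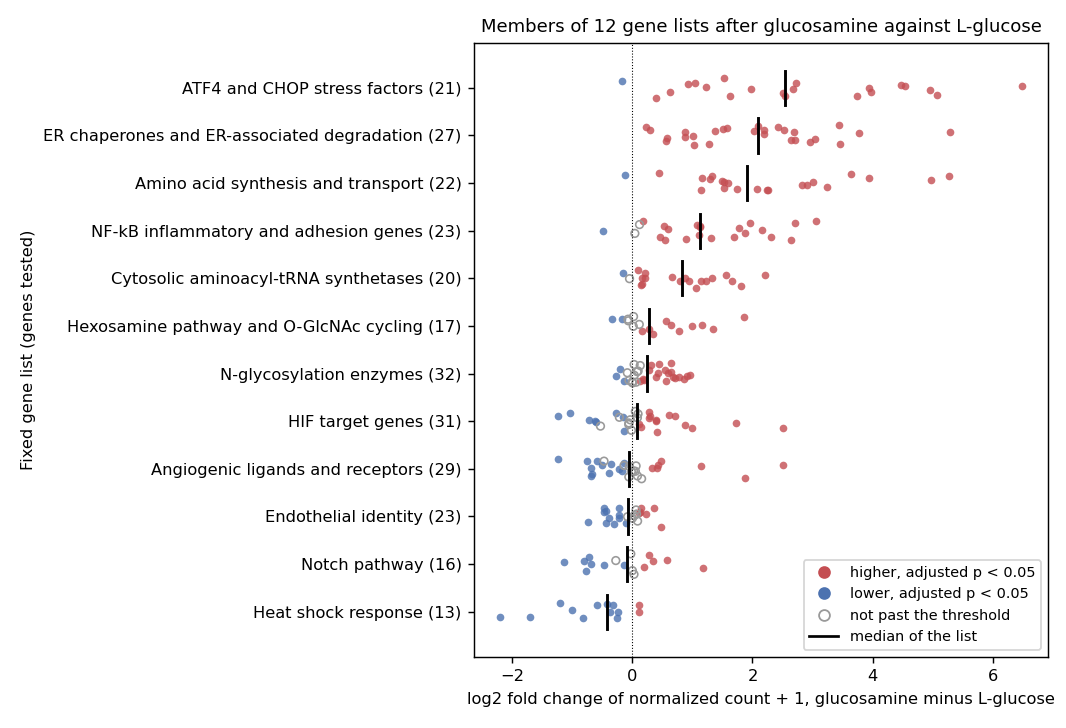
Log2 fold changes (glucosamine minus L-glucose, horizontal axis) of the tested members of 12 gene lists, 1 point per gene, filled where limma's adjusted p passed 0.05 and open where it did not; black bars are medians. All 27 ER chaperone genes lie above 0, whereas 11 of the 13 heat shock genes lie below 0 and HIF targets spread around a median of 0.08.

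Smaller rises passed the camera threshold in 6 further lists, none of which passed with an estimated correlation. Ribosomal proteins of the cytosol rose in 28 of 30 members and fell in 0 (30 and 0 adjusted over the list alone), with a median log2 fold change of 0.20, or 0.08 with total-count scaling, where 16 rose (adjusted p = 9.4e-06, and 0.70 with an estimated correlation). Of 16 NRF2 antioxidant genes 12 rose and 0 fell, also when adjusted over the list alone, among them OSGIN1 2.21-fold and HMOX1, which degrades heme, 1.44-fold (adjusted p = 5.5e-04, and 0.44 with an estimated correlation). Autophagy and lysosome genes rose in 10 of 17 members and fell in 1 (11 and 1 adjusted over the list alone), with WIPI1 up 4.41-fold (adjusted p = 0.0057, and 0.55 with an estimated correlation). The p53 list had 12 of 16 members higher and 3 lower (12 and 4 adjusted over the list alone). Its camera adjusted p was 0.025, and 0.45 with an estimated correlation. The death genes PMAIP1 and BBC3 rose 2.33-fold and 1.84-fold, while TP53INP1 and BTG2 fell by 0.62 and 0.48 on the log2 scale. Matrix and basement membrane genes rose in 12 of 20 members and fell in 2 (12 and 3 adjusted over the list alone), and TGF-beta and mesenchymal genes in 11 of 18 with 3 lower (13 and 3). Their camera adjusted p-values were 0.022 and 0.038, and 0.55 and 0.44 with an estimated correlation. With total-count scaling the autophagy, matrix and TGF-beta lists did not pass (0.063, 0.071 and 0.070), with 7, 8 and 8 members higher and 4, 6 and 5 lower, and the NRF2 and p53 lists had 9 and 9 higher and 2 and 4 lower. The TGF-beta list also did not pass with the replicate block (0.082) or with edgeR (0.11), nor without L-glucose replicate 2 or 3 (0.072 and 0.053) or glucosamine replicate 2 or 3 (0.059 and 0.051).

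The other tested lists did not pass the camera threshold. Sterol genes had 11 of 23 members higher and 5 lower (adjusted p = 0.057), with STARD4, a cholesterol carrier, up 3.62-fold, and the list was called higher without L-glucose replicate 3 (0.035) and without glucosamine replicate 1 or 3 (0.047 and 0.050), with upper-quartile scaling, without the filter, and with voom, edgeR, DESeq2 and fry. Mitochondrially encoded transcripts had 7 of 13 higher and 0 lower (adjusted p = 0.061, and 0.014 without glucosamine replicate 3), and were also called without the filter, with upper-quartile scaling and with voom. Glycolysis genes had 9 of 23 higher and 6 lower (0.74), nuclear-encoded oxidative phosphorylation genes 7 of 26 higher and 3 lower (0.52), and mTORC1 and ribosome biogenesis genes 8 of 17 higher and 2 lower (0.27). Cell cycle genes had 9 of 28 higher and 12 lower (0.69), with CDC6 up 4.32-fold and CCNE1 down 2.08-fold, a median log2 fold change of -0.05 and a mean of 0.00; with total-count scaling 6 rose and 16 fell. Immediate early genes had 7 of 16 higher and 6 lower (0.49), with NR4A2 up 3.75-fold, and YAP and TEAD targets 7 of 12 higher and 3 lower (0.27); fry called both higher (2.1e-04 and 0.0018). Adjusted over the list alone these counts were the same in each of these 8 lists. The medians of the sterol, mitochondrially encoded, glycolysis, oxidative phosphorylation, mTORC1 and immediate early lists were above 0 with the authors' scaling and below 0 with total-count scaling. Counts turned as well with that scaling, to 3 higher and 12 lower for glycolysis, 3 and 10 for oxidative phosphorylation and 4 and 5 for mTORC1 and ribosome biogenesis, and were 11 and 8 for sterol, 2 and 2 for mitochondrially encoded and 5 and 6 for immediate early genes.

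Several of the largest single changes lay outside the lists. The cadherin CDH15 (chromosome 16, 89171767 to 89195492) rose 40.2-fold from 44.4 ± 2.94 normalized counts, and ERFE, which encodes the hormone erythroferrone, rose 26.7-fold. KLHL30-AS1, an antisense RNA gene close to ERFE on chromosome 2 (238152889 to 238155994, with ERFE from 238158982 to 238168900), rose 26.8-fold from 3.76 ± 3.35. The GTPase RAB39B rose 26.5-fold and the homeobox gene DLX3 46.3-fold. Another of the 12 largest rises, the stress gene NUPR1, 31.3-fold from 3.68 ± 1.53, belongs to the ATF4 and CHOP list. SELPLG, the ligand of P-selectin on leukocytes (chromosome 12, 108622277 to 108633959), fell from 244 ± 5.98 to 26.2 ± 9.06, or 9.36-fold. Lower by 3.81-fold to 4.67-fold were the transporter SLC6A16, the receptor partner TRIL, the palmitoyltransferase ZDHHC11, the transcription factor BCL11B and the long noncoding RNA SWINGN. The remaining 5 of the 12 largest falls among genes with a symbol were copies of the U2 and U3 RNA genes, SNORD3B-1, SNORD3B-2, U3.17, RNU2-63P and U2.14, whose reads can be shared between copies. With the same filters, 6 genes with only an identifier fell at least as much as the smallest of these 12 falls. Another 1 rose at least as much as the smallest of the 12 largest rises.

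Markers of blood cells were close to 0 in these libraries. Endothelial identity genes had a mean of 38887 ± 1188 normalized counts per gene after L-glucose and 38566 ± 473 after glucosamine. Leukocyte markers had 4.23 ± 1.11 and 2.91 ± 0.295, with 2 of 11 tested and 0 called, and erythroid markers 0.919 ± 0.401 and 0.267 ± 0.270, with 0 of 8 tested. Smooth muscle and fibroblast markers, 12 tested, had 3 higher and 0 lower (MYH11, RGS5 and TAGLN, camera adjusted p = 0.89), and their median and mean log2 fold changes were -0.12 and -0.11 with a fry direction of higher. RGS5, at 119151 ± 3350 and 128936 ± 3005, made up most of their counts. Epithelial markers had 1 of 6 tested members higher, the keratin KRT18, and 1 lower, CLDN4 (camera adjusted p = 0.61, fry lower with 0.0011). Of 4 tested lymphatic endothelial markers LYVE1 and RELN rose and PROX1 fell by 0.68 on the log2 scale. Adjusted over the list alone, the counts of these marker lists were the same. With total-count scaling KRT18, LYVE1, RGS5 and TAGLN lost their calls, and the smooth muscle, epithelial and lymphatic lists had 1, 0 and 1 members higher and 2, 2 and 2 lower.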

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

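Total-count scaling and the weight per group were chosen after seeing the data, and no adjusted p-values of the authors' own were used here. Counts of calls stayed within 1.5 times in each alternative except 2. Total-count scaling gave 3858 genes higher, since it divides each library by its own total, which lowers glucosamine values relative to L-glucose values. A 2-fold minimum left 912 higher and 709 lower. Leaving out 1 library gave 5081 to 5849 genes higher and 5034 to 5738 lower, with fewer samples in the fit. The replicate block gave 6085 higher, 5920 lower, 13 lists higher and 1 lower, although libraries with the same number did not deviate together (correlations -0.01, 0.02 and 0.00). With limma and an estimated correlation in camera, 0 lists were higher and 0 lower (3 at an unadjusted p under 0.05, 25 past fry). The ATF4, amino acid, ER chaperone and hexosamine lists then had an adjusted p of 0.39, against at most 0.0073 under the other alternatives, and fry called 5 lists lower instead of 1. HIF targets passed with edgeR (0.024), DESeq2 (0.012) and fry (0.0011), and lay between 0.18 and 0.78 otherwise. Angiogenic genes, lower with the chosen camera test and not called with camera in any setting (0.29 to 0.81), were called higher with fry (8.2e-04); the cause was not tested. Of 3487 values of 184 named genes, 3438 kept the call in its direction or stayed uncalled, 42 lost the call (mostly small changes, as in ALDH18A1, AMDHD2, TAGLN and HSPD1), 4 gained it and 3 reversed, namely RGS5, HSPD1 and HSP90AB1 with total-count scaling (log2 fold changes -0.0043, -0.0035 and -0.015). In the 10 splits of the 6 libraries into 3 and 3, only 1 split, the real one, reached 11599 genes (5883 higher, 5716 lower), and the highest other count was 0 in each case; for lists the real split gave 15 and the highest other 10, also 1 of 10. With 10 splits no share under 0.05 can be reached. Other splits called 5 to 10 lists with 0 genes called. Each set 2 libraries of a group and 1 of the other against the rest. Part of the treatment difference thus stays in the contrast, and the remainder widens the spread within each side. These counts therefore do not show what would be called without a treatment effect, and do not rank list calls against gene calls. In the simulated counts, where only a small part of the genes was changed, the test found 62.0% of 1.5-fold changes. In the real comparison 46.5% of the tested genes were called. The Benjamini-Hochberg adjustment is stricter when fewer genes change, so the simulated rate does not carry over to this comparison. How many small changes were missed here was not measured.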

Other observations

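The families in this paragraph and the next were chosen after the values were seen, and the adjusted p-values cover 8 families. Many genes of transport between the endoplasmic reticulum and the Golgi, in both directions, were higher after glucosamine: of 29 tested COPI, COPII and TMED transport proteins 21 rose, 1, TMED8, fell and 7 were not called (camera adjusted p = 2.5e-05, and 0.43 with an estimated correlation). SEC23B and SEC24D of the COPII coat rose 2.56-fold and 2.42-fold and the cargo receptor TMED7 2.40-fold. Protein disulfide isomerases, which form and rearrange disulfide bonds, rose in 14 of 17 members and fell in 0 (adjusted p = 1.6e-06, and 0.35 with an estimated correlation), with PDIA4 up 5.77-fold, TXNDC11 2.14-fold and ERP44 2.01-fold. Fixed lists already held 1 gene of the first family and 3 of the second, and outside them 20 of 28 and 11 of 14 members rose. Replication-dependent histones rose in 30 of 61 members and fell in 7 (0.011, and 0.64 with an estimated correlation), with a median log2 fold change of 0.14, or 0.02 with total-count scaling.

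Several families of developmental transcription factors, chosen after their values were seen, had unequal counts of higher and lower genes. None of these families passed with an estimated correlation. Of 29 HOX genes 14 fell and 6 rose (camera adjusted p = 0.010, and 0.43 with an estimated correlation). HOXB9 rose 5.70-fold, from 158 ± 7.97 to 903 ± 40.6 normalized counts (SD, n = 3), while its neighbours HOXB8 and HOXB7 fell by 0.68 and 0.74 on the log2 scale and HOXA7 fell by 1.16. SOX factors fell in 7 of 13 members and rose in 0 (0.013, and 0.21 with an estimated correlation), with SOX4, SOX7 and SOX13 lower by 1.41-fold, 1.39-fold and 1.45-fold. KLF factors rose in 9 of 14 members and fell in 3 (0.013, and 0.21 with an estimated correlation), with KLF9 up by 1.14 and KLF7 by 0.79 on the log2 scale beside KLF2 and KLF4. Fixed lists already held 2 SOX and 4 KLF genes, and outside them 5 of 11 SOX genes fell and 6 of 10 KLF genes rose, with 2 lower. Kinesins fell in 16 of 36 members and rose in 6 (0.034, and 0.43 with an estimated correlation), and numbered zinc finger proteins fell in 153 of 439 and rose in 98 (0.10, and 0.43).

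Of the tests in the next 3 paragraphs, those of intronic position and of features in hosts with little change were set before their results were seen, and all others, including that of scaling, after. Reads at a set of 15 snRNA, U3 and U13 genes were mostly lower after glucosamine: 13 fell and 0 rose, with a median log2 fold change of -1.09 (95% bootstrap interval -1.33 to -0.54). The falls were uneven, from RNU4-2 (-0.23) and RNU1-1 (-0.56) to RNU5A-1 (-1.09), the U13 gene SNORD13 (-1.91) and the U3 gene SNORD3B-2 (-2.34). RNU4-1 (-0.12) was not called, and SNORD3A varied widely in L-glucose (39025 ± 24279 normalized counts, SD, n = 3). The 39 other snoRNA and scaRNA genes did not fall as a set, with a median of 0.12 (0.04 to 0.16), or 0.0055 with total-count scaling. RMRP and RN7SL1 did not fall either (-0.01 and 0.16), but with total-count scaling RMRP was called lower (-0.13, limma adjusted p = 0.035). Whether reads at the 39 genes came from the mature RNA or from longer transcripts around them was not tested. They therefore do not decide whether the yield of mature short RNA was lower. Sharing of reads between near-identical copies stays open, since only 3 members were taken as single-copy (median -0.99), 1 of them U13 and 1, RNU6ATAC, not called. Precursor length, poly(A) tailing and RNA selection in the kit were not tested, nor was any biological explanation.

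Short RNA features and processed pseudogenes inside introns of protein-coding genes were slightly higher after glucosamine, with a median log2 fold change of 0.20 (95% bootstrap interval 0.18 to 0.22) over 2119 features, 429 of them higher and 58 lower. Induction of the host genes was tested on 559 features in hosts with an absolute log2 fold change of at most 0.1, which had a median of 0.17 (0.13 to 0.19), above the bound of 0.1 set against it, but 0.049 with total-count scaling, which crosses the bound of 0.05 set for it. With that scaling the hosts themselves had a median of -0.12. Feature minus host was 0.16 with both scalings (0.13 to 0.19 with the authors' scaling). Their agreement was fixed in advance, since a factor per library moves feature and host alike and cancels in the difference. For the same reason such a factor cannot produce this gap. The gap itself argues only against a rise of host counts as its whole cause. Host transcription was not measured, so a rise that does not show in host counts stays open. Features more than 10 kb from any protein-coding gene had a median of 0.11 over 720 features (-0.0084 with total-count scaling). This was 0.088 below the intronic one (p = 1e-05 in a permutation of features, not libraries, the smallest that 100000 permutations can give). The gap was smaller than the 0.1 set to exclude genomic DNA or other evenly spread reads. The size of the rise still depends on the scaling (an intronic median of 0.083 with total-count scaling). Evenly spread reads and a change in unspliced RNA cannot be told apart here, since the gap to distant features fell between its bounds. Pseudogenes were not separated from the other features. Whether they shared reads with the genes they were copied from was not tested.

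VEGFA rose by 2.50 on the log2 scale, and the question was whether it rose with HIF targets in general. The other 30 HIF targets had a median of 0.066 (95% bootstrap interval -0.11 to 0.27). The limit of 0.63 was set after the values were seen, from VEGFA, the largest change in the list. The values argue only against a rise of these targets as a set by 0.63 or more. A smaller general rise is not excluded. The list with VEGFA was called higher with edgeR, DESeq2 and fry (adjusted p = 0.024, 0.012 and 0.0011) but not with the main camera test (0.32). With 3 other scalings the log2 fold change of VEGFA was between 2.39 and 2.52. A path through ATF4, whose mRNA and targets rose in the same libraries, may be involved, but no library used here had ATF4 removed, so that was not tested.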
